A study of Mus musculus with 18 samples.

How the data were processed

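The series measured RNA from intestinal epithelial cells of 6 female mice that carry a histone H2B-YFP fusion under the Cyp1a1 promoter, which βNF (beta-naphthoflavone, an agonist of the aryl hydrocarbon receptor) switches on for a time. Per the series design text, cells were taken 10 days after induction, stained with an antibody to CD24 and with the lectin UEA-1, and sorted into 3 populations per mouse. Paneth cells were positive for CD24 and UEA-1. YFP-LRCs, the label-retaining cells, were positive for CD24, negative for UEA-1 and still bright for YFP. LCCs were positive for CD24 and negative for both UEA-1 and YFP. Per the sample labels, the mice were 99 to 109 days old, and per the series design text 30000 cells were sorted for each population. Per the sample labels, 8 ng of RNA was amplified with a whole-transcript kit (NuGEN) and hybridised to Affymetrix Mouse Exon 1.0 ST arrays, 1 array per population and mouse, 18 arrays in all.

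The values used are the log2 values that the authors deposited. Per the file headers, the authors made them with Affymetrix Power Tools 1.12.0 by the RMA method (background correction, quantile normalization of all arrays together, and median polish over the probes of each probe set), for the core probe sets of the mm9 mouse genome build. The deposited summary table and the value table of the series hold the same 229581 probe sets on 18 arrays, with a largest difference of 0 between them. No scan date, hybridisation batch or RNA quality score is given, so no analysis within batches was possible. For arrays, the number of replicates, 6 per population, limits the precision.

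The probe table paired 209279 probe sets with exactly 1 gene symbol. The 4446 probe sets with several symbols and the 15856 with none were left out, because their signal cannot be assigned to 1 gene. Of 16380 symbols, 14190 matched a current mouse symbol and 2145 matched through a synonym in a gene table of the GRCm38.p6 assembly. That table was used for names alone, since its assembly differs from mm9, and no coordinate is printed. The 45 symbols without a match kept the name the probe table gives. A gene's value on an array was the median over its probe sets. This gave 16358 genes with a median of 11 probe sets per gene; 15207 genes had at least 3 probe sets and 536 had 1. Probe set values ran from 1.41 to 15.9, and the gene values had a median of 6.54. No filter on low values was applied. Olfm4 and Cd24a, which were to be named in any case, have no probe set of their own and were not analysed here.

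Gene differences were tested with limma: a mean per population over all 18 arrays, empirical Bayes moderation, 2-sided tests, and Benjamini-Hochberg adjustment over the 16358 genes in each of the 3 comparisons. A gene was called at an adjusted p under 0.05. Errors after a log2 difference are standard errors from this fit (n = 6 arrays per population), and errors after a group mean are standard deviations. A population marker was a gene called, with at least a 2-fold difference in the same direction, against both of the other populations. Lists of genes were tested with camera from limma at a preset correlation of 0.01, adjusted over all 66 tests (22 lists, 3 comparisons), and again with a correlation estimated from the data and with fry. The camera test compares the list's genes with all other genes, so a list can pass it when few members are called.

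The 22 lists covered Paneth cell, crypt base columnar stem cell, position +4 or reserve stem cell, Wnt target, Notch pathway, secretory progenitor, enteroendocrine transcription factor, enteroendocrine hormone and granule, goblet cell, tuft cell, absorptive enterocyte, S phase, G2 and mitosis, cyclin-dependent kinase inhibitor, aryl hydrocarbon receptor target, endoplasmic reticulum stress and secretion, immediate early and dissociation stress, T cell, B and plasma cell, myeloid cell, stromal and endothelial, and red blood cell genes. They came from general knowledge of these cell types, and some genes stand in several lists. The list median, the list mean and the direction of the test differed in sign in 7 of the 66 tests and in 0 of the called ones.

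The place of YFP-LRC between the other populations was scored per mouse. Genes called with at least a 2-fold difference between Paneth and LCC in the other 5 mice were averaged on the arrays of the held-out mouse, signed by direction, and scaled so that its LCC array is 0 and its Paneth array is 1. The unscaled scores were compared with an exact paired sign-flip permutation test, 2-sided, over 6 mice. Exon usage was tested with diffSplice from limma on probe sets whose mean was above the median of all values in both populations, for genes with at least 3 such probe sets, with a Simes p per gene.

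The comparisons, the tests, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Under that rule, the text may name the 10 largest called changes per direction in each comparison (changed the same way in all 6 mice, at least 3 probe sets, above the median level), 8 markers per population and direction, up to 4 members per list and comparison, 3 genes per comparison for exon usage, and 30 genes whatever their values. The text prints fewer genes than the rule allows. Which list members are printed was decided after their values and their stability were seen, with preference for calls that hold when any 1 array is left out, so the printed members are on the whole steadier than their lists. Of all genes that the rule names and that were called, 26 of 53 in YFP-LRC against LCC, 2 of 24 in YFP-LRC against Paneth and 9 of 69 in Paneth against LCC lost the call when some single array was left out. When some whole mouse was left out, 39, 8 and 18 did.

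The first set of alternatives was the mouse as a fixed or a random term, the mean in place of the median over probe sets, stricter filters on probe sets and genes, a second quantile normalization, centring of arrays, another moderation of the variance, array weights, the 12 arrays of a comparison alone, the second deposited table, and leaving out each mouse. Alternatives chosen after seeing the data were leaving out each single array, leaving out the LCC arrays of mice 5 and 6 or of mice 2, 3, 5 and 6, a covariate for array quality, array weights per population, another exon test, and the ratio of mean differences for the position score. The covariate was the residual spread of an array: for genes with at least 5 probe sets, the median absolute value left after the gene's value on that array and then the mean of the probe set over the arrays were subtracted. Arrays of the same mouse are not forced to be alike in the tests above. This was checked once, with the mouse as given by the replicate number, because the design text says that the 3 populations came from each of 6 mice. Correlations of gene values centred within populations ran from 0.0154 to 0.406 for YFP-LRC and LCC arrays of the same mouse, and the array of the same mouse was the best match for 4 of 6. For YFP-LRC and Paneth they ran from 0.0413 to 0.175 (4 of 6), and for Paneth and LCC from -0.114 to 0.177 (2 of 6). The consensus correlation within mice was 0.0590. The label of the YFP-LRC array of mouse 6 carries another litter code than the other arrays of that mouse, and the label of the LCC array of mouse 1 carries an added suffix. The replicate number was followed in both cases.

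The steps were tested on simulated data with the spread of each population. With 50 changed genes per fold size among 16358, limma recovered 72% of 2-fold changes in YFP-LRC against LCC, 72% in YFP-LRC against Paneth and 80% in Paneth against LCC. For 1.5-fold changes it recovered 22%, 28% and 32%, and for 4-fold changes 98% in each. It made 36, 7 and 28 false calls. With 1 spread shared by the populations it made 12, 8 and 13. The unequal spread of the populations thus let more unchanged genes pass in the comparisons with LCC, and a part of the gene calls there is in doubt. The diffSplice test recovered 81 of 100 4-fold exon changes in YFP-LRC against LCC, 71 in YFP-LRC against Paneth and 80 in Paneth against LCC, with 343, 18 and 299 false calls among 10894, 10929 and 10866 genes. Of 100 2-fold exon changes it recovered 28, 9 and 25. A test of each probe set minus its gene's median with its own variance, added for that reason, recovered 65, 69 and 65 of the 4-fold and 6, 7 and 13 of the 2-fold changes, with 10, 5 and 15 false calls. The camera test called 4 of 4 lists moved 1.5-fold and 0 of 18 others in each comparison, and the position score returned -0.00526, 0.506 and 0.999 for true places of 0, 0.5 and 1. Each simulated gene was drawn independently, while the correlation estimated within the real lists reached 0.577. The 0 false calls of camera thus do not cover genes that move together. Simulated position scores had an SD of 0.0150 to 0.0256, against 0.265 in the data. Analyses used R 4.3.3, limma 3.58.1, jsonlite 2.0.0 and the package data.table (version 1.17.8), and figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.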

Results

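The data are log2 values for 16358 genes on 18 arrays, from 3 populations of intestinal epithelial cells sorted from each of 6 mice. The 6 arrays of each population are the replicates. YFP-LRCs kept the histone label for 10 days, which cells lose by dividing. LCCs came from the same CD24-positive, UEA-1-negative gate without the label. Paneth cells, which secrete antimicrobial proteins at the crypt base, were sorted as positive for CD24 and UEA-1. Per the design text, the comparison was made to find unique markers of each population. The median probe set value was 6.40 to 6.66 on the LCC arrays, 6.63 to 6.77 on the Paneth arrays and 6.65 to 6.73 on the YFP-LRC arrays.

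The 2 measures used for array quality moved with the LCC population. Both set an array against all others, most of them not LCC, so a true difference of the LCC population would move them too. A covariate for residual spread can then take up part of a population difference. The median correlation of an array with the other 17 arrays was 0.938, 0.894, 0.886, 0.928, 0.872 and 0.825 for the LCC arrays of mice 1 to 6. It was 0.929 to 0.947 for Paneth and 0.916 to 0.950 for YFP-LRC. The residual spread of probe sets ran from 0.320 to 0.539 in LCC, 0.279 to 0.404 in Paneth and 0.298 to 0.368 in YFP-LRC. The LCC arrays of mice 2, 3, 5 and 6 thus correlated less with the others than any array of the other populations. The median standard deviation of a gene was 0.371 in LCC, 0.283 in Paneth and 0.288 in YFP-LRC. The first principal component held 31.7% of the variance and the second 9.84%.

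**Figure D1:**
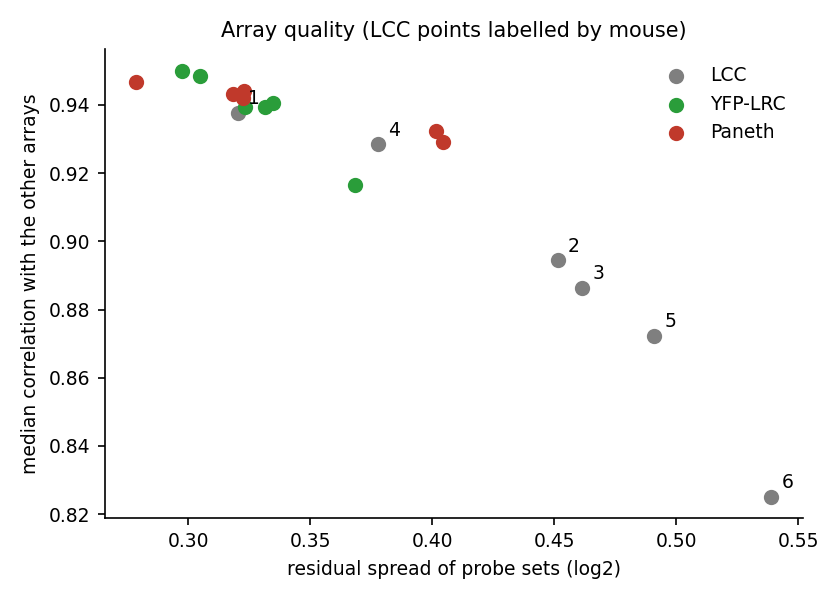
Residual spread of the probe sets of each array against its median correlation with the other arrays, 6 arrays per population, with the LCC arrays labelled by mouse. The LCC arrays reach a residual spread of 0.539 and a correlation of 0.825, and those of mice 1 and 4 lie among the other populations.

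The comparison of YFP-LRC with LCC asks what sets label-retaining cells apart from their unlabelled neighbours in the same gate. Lgr5, a receptor for R-spondins that marks crypt base columnar stem cells, was higher in YFP-LRC by 1.61 ± 0.20 log2 (adjusted p = 0.00065; 9.62e-06 to 0.187 over the alternatives). Its means were 6.96 ± 0.47 in LCC, 9.23 ± 0.27 in Paneth and 8.57 ± 0.25 in YFP-LRC. The goblet mucin Muc2 was higher by 1.29 ± 0.19 (adjusted p = 0.0024), the Paneth cell metalloprotease Mmp7 by 1.02 ± 0.21 (adjusted p = 0.011) and Atoh1, the transcription factor of the secretory lineage, by 0.93 ± 0.22 (adjusted p = 0.0194). Their adjusted p ran from 0.00067 to 0.307, 0.00154 to 0.147 and 0.00769 to 0.373 over the alternatives. Among the lower genes, the G protein regulator Rgs1 changed by -2.89 ± 0.50 (adjusted p = 0.00443), the granule proteoglycan Srgn by -1.40 ± 0.31 (adjusted p = 0.0132), the chemokine Cxcl2 by -1.25 ± 0.25 (adjusted p = 0.00943) and the cytokine Il1b by -0.93 ± 0.22 (adjusted p = 0.0181).

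Of 16358 genes, 1035 were higher and 150 lower in YFP-LRC than in LCC, so 87.3% of the calls were higher. After a second quantile normalization they were 378 and 236 (61.6% higher), and with each array centred 610 and 295 (67.4%). At least 2-fold changes numbered 265 higher and 8 lower (102 and 23 after the second quantile normalization, 137 and 17 with centring). The unadjusted count was 4060, and 934 called genes changed the same way in all 6 mice. Beside Lgr5, the largest increases under the naming rule were Tanc2 (1.68), Spa17 (1.68), Dnajc1 (1.62), Cep350 (1.59), Tceal8 (1.57), Mettl1 (1.56), Rab1b (1.54), Ano10 (1.52) and U2af2 (1.52). Tceal8 had an adjusted p of 0.0535 without the YFP-LRC array of mouse 5. C1qtnf4 was lower (-0.87 ± 0.19, adjusted p = 0.0144), and so were Nkx2-4 (-0.89), Mrfap1 (-0.88), ATP6 (-0.84), Igfbp3 (-0.83) and Ankrd46 (-0.83). Without single arrays among LCC 2, 3, 5 and 6, Paneth 2, 3, 4 and 6 and YFP-LRC 1 to 5, the last 5 of these reached adjusted p of 0.0705, 0.102, 0.102, 0.0896 and 0.0791. C1qtnf4 kept its call without any 1 array, but leaving out 1 mouse ended it for 4 of 6 mice (up to 0.0648).

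The number of calls in YFP-LRC against LCC rested on single arrays. The 1035 higher genes became 1762 without LCC 1, 563 without LCC 3, 512 without LCC 5 and 495 without LCC 6. They became 601, 644, 466 and 493 without YFP-LRC 1, 2, 4 and 5. The 150 lower genes became 394, 88, 63, 234, 75 and 64 without LCC 1 to 6, and 48, 77, 50 and 51 without YFP-LRC 1, 2, 4 and 5. The 265 genes at least 2-fold higher became 542, 469, 166 and 143 without LCC 1, 4, 5 and 6, and 150 and 171 without YFP-LRC 4 and 5. The 8 at least 2-fold lower became 27 and 19 without LCC 1 and 4, and 5 without YFP-LRC 1 (Rgs1, Hbb-b1, Srgn, Cxcl2 and Obox6). With LCC 1 and 4 as the only LCC arrays, 1 gene was higher (Ppat) and 3 were lower (Gpr65, Hbb-b1 and Nmnat1). With the residual spread as a covariate, 3 were higher (Kit, Slco3a1 and Atp2a3) and 4 lower (Aadac, Abhd3, Galm and Glod5). These few were named after the values were seen. Of the 53 called genes that the naming rule covers, 52 lost the call with LCC 1 and 4 (Hbb-b1 is the exception) and 53 with the covariate. Of all 1185 called genes, 1185 had the same sign with the covariate, while their median absolute log2 difference went from 0.82 to 0.57 and their median standard error from 0.199 to 0.253. Lgr5 differed by 1.02 (adjusted p = 0.187) with LCC 1 and 4 and by 1.28 (adjusted p = 0.0599) with the covariate.

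**Figure D2:**
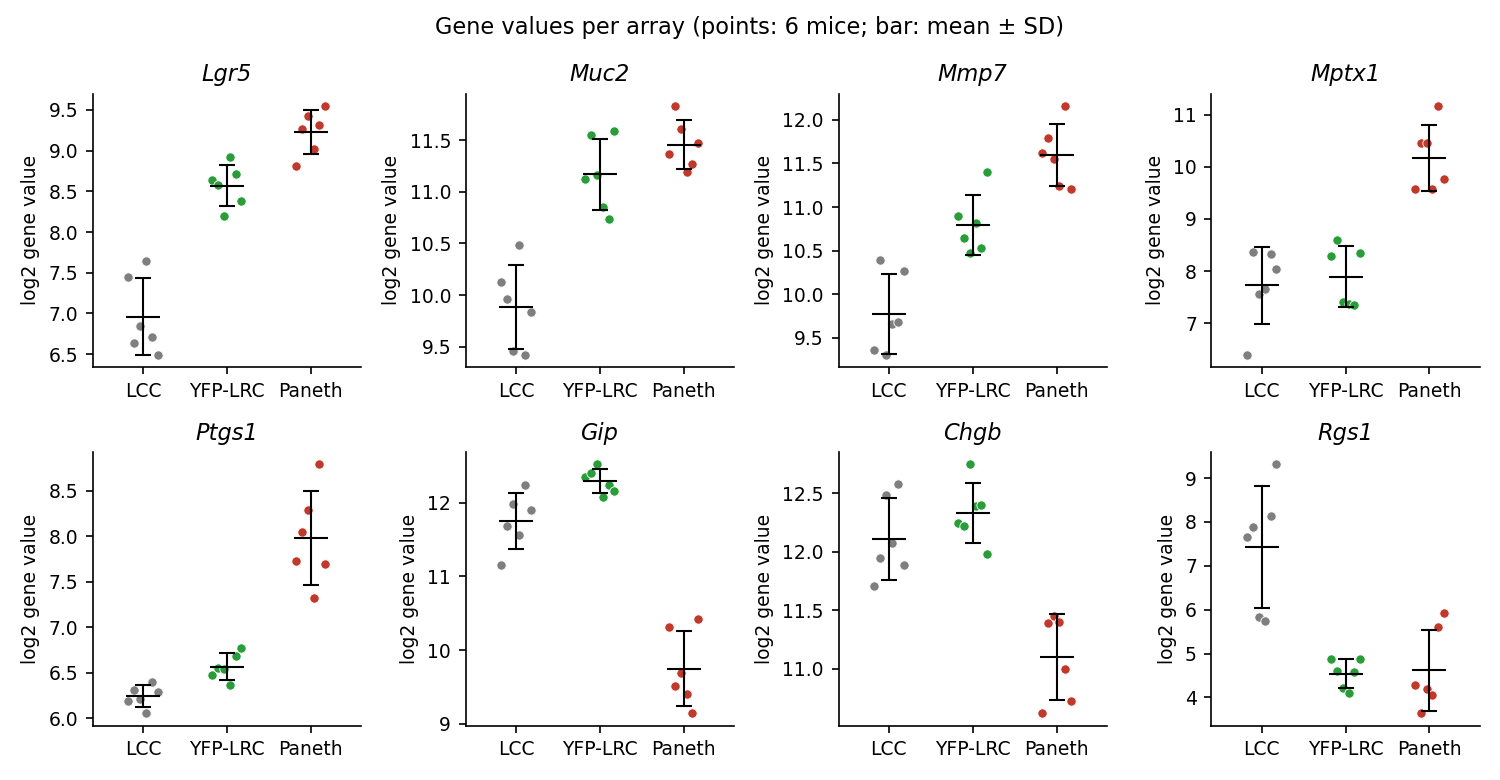
Log2 values of Lgr5, Muc2, Mmp7, Mptx1, Ptgs1, Gip, Chgb and Rgs1 in the 3 populations, with 1 point per mouse and the mean ± SD (n = 6). Lgr5 had a mean of 6.96 ± 0.47 in LCC, 8.57 ± 0.25 in YFP-LRC and 9.23 ± 0.27 in Paneth.

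Of the stem cell, Wnt and secretory lists, 5 passed the camera test as higher in YFP-LRC than in LCC at the preset correlation, and 0 of these held with an estimated one. With fry, the adjusted p of these 5 ran from 6.63e-05 for Wnt targets to 0.0379 for the Paneth cell list. In the crypt base columnar stem cell list (median 0.60, adjusted p = 0.000299; adjusted p = 0.169 with an estimated correlation), of 22 measured genes 9 were called higher, 0 lower and 13 not called, and 10 higher and 0 lower adjusted over the list alone. Soat1 was higher by 1.17 ± 0.20 (adjusted p = 0.004). In the Wnt target list (median 0.52, adjusted p = 0.00146; adjusted p = 0.0747 with an estimated correlation), 7 were called higher, 0 lower and 8 not called, and 7 higher and 0 lower adjusted over the list alone. Ccnd1 was higher by 0.86 ± 0.18 (adjusted p = 0.0106). Myc (0.91 ± 0.24, adjusted p = 0.0307) lost the call without LCC 2, 5 or 6 or YFP-LRC 4 or 5 (up to 0.0787). For the goblet cell list (median 0.48, adjusted p = 0.00909; adjusted p = 0.208 with an estimated correlation), 4 were called higher, 0 lower and 10 not called, and 6 higher and 0 lower adjusted over the list alone. They were Muc2, Ern2 (1.04), Galnt12 (0.88) and Klk1 (0.97), and Klk1 lost the call without any 1 of 14 arrays, all but Paneth 3, LCC 4 and YFP-LRC 2 and 3 (up to 0.0921). For the Paneth cell list (median 0.56, adjusted p = 0.0148; adjusted p = 0.44 with an estimated correlation), 4 were called higher, 0 lower and 11 not called, and 6 higher and 0 lower adjusted over the list alone. They were Mmp7, Itln1 (1.24 ± 0.24, adjusted p = 0.00803), Pnliprp2 (1.18), lost without LCC 3 (0.0511), and Habp2 (1.06), lost without LCC 3 or YFP-LRC 1 or 2 (up to 0.0566). The endoplasmic reticulum stress and secretion list (median 0.46, adjusted p = 0.000486; adjusted p = 0.208 with an estimated correlation) was higher too, where 4 were called higher, 0 lower and 18 not called, and 7 higher and 0 lower adjusted over the list alone. They were Sel1l (0.86 ± 0.20, adjusted p = 0.0157), Dnajc3 (0.65, named after its value was seen and not recomputed without single arrays), Creb3l4 (0.87), lost without YFP-LRC 5 (0.0505), and Creb3l1 (0.78), lost without any 1 of 12 arrays, Paneth 2, 3 and 4, LCC 2, 3, 5 and 6 and YFP-LRC 1, 2, 4, 5 and 6 (up to 0.0813). Sel1l and Ern2 kept the call without any 1 array, but leaving out 1 mouse ended it for 3 and 2 of 6 mice (up to 0.084 and 0.0626). Soat1, Ccnd1, Galnt12 and Itln1 kept the call without any 1 mouse. The LCC arrays behind these 5 lists had median correlations of 0.825 to 0.938, against 0.916 to 0.950 for YFP-LRC.

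The G2 and mitosis list was higher in YFP-LRC than in LCC at the preset correlation alone (median 0.51, adjusted p = 0.0156; adjusted p = 0.669 with an estimated correlation), where 1 was called higher, 0 lower and 23 not called, and 0 higher and 0 lower adjusted over the list alone. Its 1 called gene was Plk1 (0.81 ± 0.24, adjusted p = 0.0479), whose call ended without any 1 of 14 arrays, the 6 Paneth arrays, LCC 3, 4 and 6 and YFP-LRC 1, 2, 3, 5 and 6 (up to 0.105). Mki67 was not called (0.53 ± 0.29, adjusted p = 0.258). In the S phase list, with an adjusted p of 0.0633, 0 genes were called, with 4 higher and 0 lower adjusted over the list alone. Pcna differed by 0.33 ± 0.23 (adjusted p = 0.383). The T cell list was lower (median -0.18, adjusted p = 0.0259; adjusted p = 0.144 with an estimated correlation), with 0 called members in limma. Adjusted over the list alone, it also had 0. The myeloid cell list was lower (median -0.18, adjusted p = 0.0189; adjusted p = 0.105 with an estimated correlation), where Tyrobp was the 1 called gene (-0.89 ± 0.23, adjusted p = 0.0251), lost without LCC 2, 3 or 5 or YFP-LRC 3 or 5 (up to 0.0606). The stromal and endothelial list was lower too (median -0.15, adjusted p = 0.00512; adjusted p = 0.223 with an estimated correlation), with 0 called members. The B and plasma cell list had an adjusted p of 0.0676. The G2 and mitosis list turned to the lower direction with LCC 1 and 4 as the only LCC arrays (adjusted p = 0.458) and with the covariate (adjusted p = 0.198), and its call ended without LCC 6, YFP-LRC 4 or YFP-LRC 5, the Paneth cell list call without LCC 1, LCC 4 or YFP-LRC 6, and the T cell call without YFP-LRC 5. The T cell, myeloid and stromal calls also ended with LCC 1 and 4 as the only LCC arrays and with the covariate, the goblet and secretion calls with LCC 1 and 4, the T cell, myeloid and G2 and mitosis calls without LCC 5 and 6, and the T cell call after a second quantile normalization. Over the alternatives, adjusted p ran from 3.84e-06 to 0.169 for crypt base columnar stem cell genes, 3.45e-05 to 0.0747 for Wnt targets, 0.000978 to 0.208 for goblet, 2.18e-08 to 0.44 for Paneth, 9.43e-05 to 0.208 for secretion, 0.000223 to 0.669 for G2 and mitosis, 0.00605 to 0.199 for T cell, 0.00734 to 0.126 for myeloid and 0.000159 to 0.361 for stromal genes. The higher residual spread of the LCC arrays, up to 0.539, stands beside each of these groups.

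The comparison of YFP-LRC with Paneth asks how label-retaining cells differ from the cells sorted as Paneth, and it does not use the LCC arrays for the difference. The incretin gene Gip was higher in YFP-LRC by 2.55 ± 0.21 log2 (adjusted p = 2.27e-06; 4.13e-08 to 0.0003 over the alternatives), with means of 11.75 ± 0.38 in LCC, 9.75 ± 0.52 in Paneth and 12.30 ± 0.16 in YFP-LRC. Chga and Chgb, proteins of the secretory granule, were higher by 1.30 ± 0.24 (adjusted p = 0.0123) and 1.23 ± 0.19 (adjusted p = 0.00209), and Rfx6, a transcription factor of endocrine cells, by 1.34 ± 0.25 (adjusted p = 0.0123). Ccnj fell by 2.49 ± 0.23 (adjusted p = 6.85e-06), the Paneth cell pentraxin Mptx1 fell by 2.27 ± 0.34 (adjusted p = 0.00175) and the antimicrobial gene Ang4, with 2 probe sets, fell by 2.04 ± 0.28 (adjusted p = 0.000749). Ptgs1 and Alox5, which make eicosanoids in tuft cells, changed by -1.41 ± 0.18 (adjusted p = 0.000387) and -1.10 ± 0.19 (adjusted p = 0.00737). Leaving out 1 mouse ended the calls of Chga (for 2 of 6 mice), Rfx6 (3) and Alox5 (2), with adjusted p up to 0.117, 0.136 and 0.0654. Lgr5 was not called (-0.66 ± 0.20, adjusted p = 0.302), nor were Mmp7 (-0.80 ± 0.21, adjusted p = 0.188), Lyz1 (-0.30 ± 0.12, adjusted p = 0.763) and Muc2 (-0.29 ± 0.19, adjusted p = 0.994).

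In YFP-LRC against Paneth, 9 genes were higher and 49 lower, of which 8 and 36 changed at least 2-fold. The unadjusted count was 903, and 58 genes changed the same way in all 6 mice. Other higher genes were Fabp5 (1.70), Nefm (1.53), Etv1 (1.21) and Kcnj3 (1.11 ± 0.24, adjusted p = 0.0455). Other lower genes were Cd300lf (-2.02), Ptprc (-1.99), Plek (-1.97), Fbxl21 (-1.85), Strip2 (-1.73), Ces1c (-1.70) and Siglec5 (-1.47). Kcnj3 lost the call with the mouse as a block (adjusted p = 0.082) and without any 1 of 13 arrays, Paneth 1, 3, 4 and 5, LCC 1, 2, 3, 4 and 6 and YFP-LRC 2, 3, 4 and 6 (up to 0.145). The tyrosine phosphatase Ptpn6 (-1.12 ± 0.23, adjusted p = 0.0341) lost it without Paneth 2, 3 or 6 or YFP-LRC 1, 2, 4, 5 or 6 (up to 0.108).

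The tuft cell list was lower in YFP-LRC than in Paneth (median -0.83, adjusted p = 1.03e-27; adjusted p = 0.0215 with an estimated correlation), where 0 were called higher, 6 lower and 13 not called, and 0 higher and 14 lower adjusted over the list alone. Matk was among the called (-1.09 ± 0.19, adjusted p = 0.00793), while Dclk1 was not (-0.72 ± 0.25, adjusted p = 0.495). The Paneth cell list was lower (median -0.80, adjusted p = 2.51e-18; adjusted p = 0.0215 with an estimated correlation), where 0 were called higher, 2 lower and 13 not called, and 0 higher and 9 lower adjusted over the list alone. The called genes were Mptx1 and Ang4. The enteroendocrine hormone and granule list was higher (median 0.38, adjusted p = 6.35e-14; adjusted p = 0.0215 with an estimated correlation), where 3 were called higher, 0 lower and 23 not called, and 9 higher and 0 lower adjusted over the list alone. The called genes were Gip, Chga and Chgb. The enteroendocrine transcription factor list was higher as well (median 0.20, adjusted p = 3.78e-07; adjusted p = 0.044 with an estimated correlation), with Rfx6 and Etv1 called, 12 not called, and 6 higher and 0 lower adjusted over the list alone. The endoplasmic reticulum stress and secretion list was lower (median -0.15, adjusted p = 0.000192; adjusted p = 0.186 with an estimated correlation), with 0 members called and 0 higher and 4 lower adjusted over the list alone. The goblet cell list was lower (median -0.27, adjusted p = 0.0259; adjusted p = 0.264 with an estimated correlation), with 0 members called and 1 higher and 1 lower adjusted over the list alone; its call ended without Paneth 2 or 5 or YFP-LRC 3, 4 or 5, and after a second quantile normalization. Over the alternatives, adjusted p ran from 2.54e-32 to 0.0215 for tuft, 5.92e-25 to 0.0215 for Paneth, 3.87e-16 to 0.0215 for hormone, 3.68e-11 to 0.044 for transcription factor, 8.3e-06 to 0.186 for secretion and 0.00782 to 0.264 for goblet genes. The lists not called were crypt base columnar stem cell (0.135), Wnt target (0.682), S phase (0.162), G2 and mitosis (0.0876), T cell (0.927), B and plasma cell (0.162), myeloid (0.496) and stromal (0.271).

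The comparison of Paneth with LCC gives the reference difference between the cells sorted as Paneth and the unlabelled gate. Ccnj was higher in Paneth by 3.17 ± 0.23 log2 (adjusted p = 1.95e-07; 2.96e-08 to 0.000428 over the alternatives). Mptx1 was higher by 2.44 ± 0.34 (adjusted p = 0.000149), Mmp7 by 1.82 ± 0.21 (adjusted p = 3.35e-05) and Muc2 by 1.58 ± 0.19 (adjusted p = 4.68e-05). Lgr5 was higher by 2.27 ± 0.20 (adjusted p = 2.18e-06), and its adjusted p ran from 2.69e-08 to 0.00122 over the alternatives. The tuft cell kinase gene Dclk1 was higher by 1.34 ± 0.25 (adjusted p = 0.00168) and Ptgs1 by 1.74 ± 0.18 (adjusted p = 1.13e-05). Gip fell by 2.01 ± 0.21 (adjusted p = 1.13e-05; 1.97e-06 to 0.0101), the hormone gene Cck fell by 1.14 ± 0.27 (adjusted p = 0.00963) and Rgs1 fell by 2.81 ± 0.50 (adjusted p = 0.00141). Lyz1, which encodes lysozyme, was not called (0.34 ± 0.12, adjusted p = 0.072), with means of 13.09 ± 0.19 in LCC, 13.43 ± 0.16 in Paneth and 13.13 ± 0.15 in YFP-LRC.

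In Paneth against LCC, 1958 genes were higher and 414 lower (82.5% of calls higher), of which 657 and 28 changed at least 2-fold. After a second quantile normalization they were 995 and 785 (55.9% higher), and with each array centred 1389 and 983 (58.6%). The 657 became 321 and 435 under these settings, and the 28 became 45 and 46, and 47 without LCC 1. The unadjusted count was 4937, and 1449 called genes changed the same way in all 6 mice. Other large increases under the naming rule were Spa17 (2.64), Ces1c (2.53), Fbxl21 (2.49), Krt23 (2.44), Strip2 (2.32) and Sytl2 (2.21). Other large decreases were Retnlg (-1.60), Mrfap1 (-1.42), Srgn (-1.41), Nefm (-1.26), P2ry14 (-1.25) and Tbca (-1.14). Retnlg lost the call without Paneth 2, Paneth 5 or LCC 2 (up to 0.0605), and Tbca without Paneth 2 or 6 (up to 0.0523). The 414 lower genes became 721, 249, 268 and 232 without LCC 1, 3, 5 and 6, and 256, 251 and 254 without Paneth 2, 3 and 5. With LCC 1 and 4 as the only LCC arrays, 141 genes were higher and 15 lower, and with the residual spread as a covariate 380 and 72. Of the 69 called genes that the naming rule covers, 36 lost the call with LCC 1 and 4 and 26 with the covariate.

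The Paneth cell list was higher in Paneth than in LCC (median 1.71, adjusted p = 4.73e-10; adjusted p = 0.102 with an estimated correlation), where 10 were called higher, 0 lower and 5 not called, and 12 higher and 0 lower adjusted over the list alone. The tuft cell list was higher (median 1.03, adjusted p = 3.3e-12; adjusted p = 0.131 with an estimated correlation), where 15 were called higher, 0 lower and 4 not called, and 16 higher and 0 lower adjusted over the list alone. Alox5 was among them (1.59 ± 0.19, adjusted p = 3.46e-05). The endoplasmic reticulum stress and secretion list was higher (median 0.72, adjusted p = 8.74e-07; adjusted p = 0.126 with an estimated correlation), where 13 were called higher, 0 lower and 9 not called, and 16 higher and 1 lower adjusted over the list alone. Its chaperone gene Dnajb9 was higher by 2.07 ± 0.42 (adjusted p = 0.00357). The goblet cell list was higher (median 0.71, adjusted p = 0.000592; adjusted p = 0.131 with an estimated correlation), where 8 were called higher, 0 lower and 6 not called, and 8 higher and 0 lower adjusted over the list alone. Crypt base columnar stem cell genes were higher (median 0.63, adjusted p = 0.000145; adjusted p = 0.144 with an estimated correlation), where 9 were called higher, 0 lower and 13 not called, and 13 higher and 1 lower adjusted over the list alone. So were Wnt targets (median 0.44, adjusted p = 0.0148; adjusted p = 0.131 with an estimated correlation), where 5 were called higher, 0 lower and 10 not called, and 7 higher and 1 lower adjusted over the list alone. The called Wnt targets were Lgr5, Myc (0.73), Rnf43 (0.71), and Axin2 (0.65) and Ephb2 (0.48), the last 2 named after their values were seen and not recomputed without single arrays. Myc lost the call without any 1 of 13 arrays, all but LCC 1 and 4 and YFP-LRC 4, 5 and 6 (up to 0.106), and Rnf43 without any 1 of 14, all but Paneth 5 and LCC 2, 3 and 4 (up to 0.11). The LCC arrays behind these 6 lists had median correlations down to 0.825, and the Paneth arrays down to 0.929.

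The enteroendocrine hormone and granule list was lower in Paneth than in LCC (median -0.29, adjusted p = 0.000391; adjusted p = 0.183 with an estimated correlation), where 1 was called higher, 8 lower and 17 not called, and 3 higher and 11 lower adjusted over the list alone. Its 1 higher gene was Sst (1.25 ± 0.27, adjusted p = 0.00554), and Chga fell by 0.93 ± 0.24 (adjusted p = 0.0139). The enteroendocrine transcription factor list was lower (median -0.19, adjusted p = 0.0256; adjusted p = 0.264 with an estimated correlation), with 0 members called in limma, and its call ended without Paneth 1, without LCC 5 and 6, with LCC 1 and 4 as the only LCC arrays and with the covariate. The B and plasma cell list was lower (median -0.22, adjusted p = 0.0148; adjusted p = 0.183 with an estimated correlation) with Jchain as the 1 called gene (-0.73 ± 0.24, adjusted p = 0.0481), named after its value was seen and not recomputed without single arrays. The stromal and endothelial list was lower (median -0.22, adjusted p = 0.00199; adjusted p = 0.208 with an estimated correlation) with Col6a1 as the 1 called gene (-0.50 ± 0.13, adjusted p = 0.0178). With LCC 1 and 4 as the only LCC arrays the hormone and stromal calls ended, with the covariate the stromal call did, and after a second quantile normalization the Wnt target and B and plasma cell calls did. Over the alternatives, adjusted p ran from 2.75e-19 to 0.102 for Paneth, 3.85e-25 to 0.131 for tuft, 3.47e-07 to 0.126 for secretion, 0.000126 to 0.131 for goblet, 1.34e-05 to 0.144 for crypt base columnar stem cell and 6.63e-05 to 0.229 for Wnt target genes. They ran from 1.53e-06 to 0.183 for hormone, 0.00176 to 0.274 for endocrine transcription factor, 0.00408 to 0.216 for B and plasma cell and 1.06e-05 to 0.208 for stromal genes. The T cell (0.106), myeloid (0.118), S phase (0.336) and G2 and mitosis (0.235) lists were not called. Residual spread of up to 0.539 in LCC and 0.404 in Paneth stands beside these groups. In all, 4 of the 6 list calls of YFP-LRC against Paneth held with an estimated correlation, and 0 of 9 and 0 of 10 held in YFP-LRC against LCC and in Paneth against LCC. With fry, which tests a list's genes without comparing them to the other genes, 4 of 6, 8 of 9 and 9 of 10 held in the same order.

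**Figure D3:**
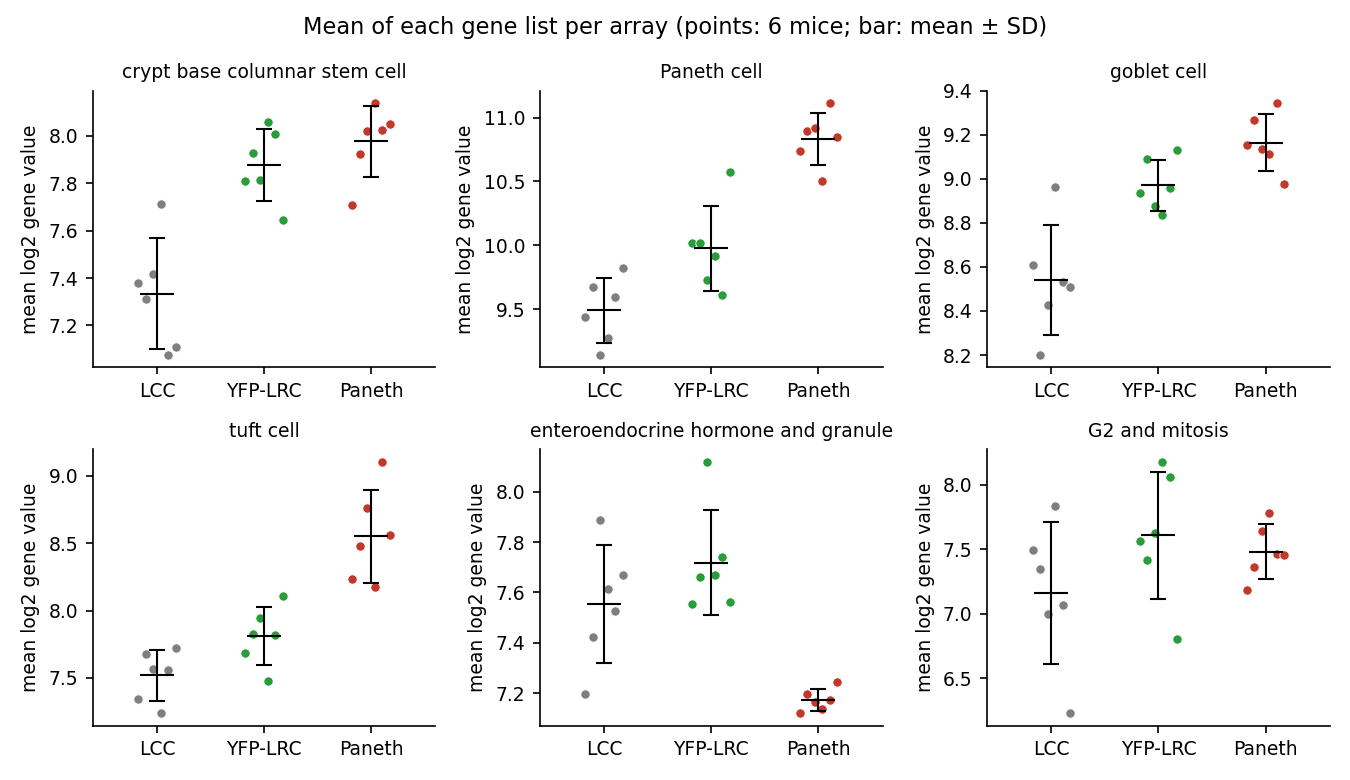
Mean log2 value of the measured genes of 6 lists in the 3 populations, with 1 point per mouse and the mean ± SD (n = 6). The median difference of YFP-LRC from Paneth was -0.83 for the tuft cell list and 0.38 for the enteroendocrine hormone and granule list.

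Markers answer which genes set 1 population apart from both others. YFP-LRC had 0 markers, higher or lower, in limma, and 0 as well at unadjusted p with a 2-fold difference. Paneth had 31 higher markers, with Ccnj, Mptx1, Cd300lf, Fbxl21, Plek, Strip2, Ces1c and C4bp the largest, and 4 lower, which were Gip, Nefm, Chgb and Fabp5. LCC had 4 higher markers: Rgs1, Srgn, Hbb-b1 with 2 probe sets, and a gene with no name beyond a sequence record, with 1 probe set. LCC had 194 lower markers, with Tanc2, Spa17, Lgr5, Cep350, Tceal8, Mettl1, Vldlr and Thbs1 the largest. With only probe sets above the median, Fabp5 was a higher YFP-LRC marker; with array weights Cyct was a lower one. Without mouse 3, Rfx6 was a higher one. The 194 became 422, 363, 128 and 101 without LCC 1, 4, 5 and 6, and 118 without YFP-LRC 4. The 4 higher LCC markers became 13 without LCC 1 and 8 without LCC 4, and the 4 lower Paneth markers became 2 without Paneth 5, Paneth 6 or LCC 5. LCC arrays, which had the lowest correlations, enter every marker.

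On genes chosen in the other 5 mice for a difference between Paneth and LCC (283 to 1073 genes), YFP-LRC lay at 0.718 ± 0.265 (SD, n = 6 mice) of the way from LCC to Paneth. The unscaled score of YFP-LRC exceeded that of LCC by 0.669 ± 0.256 log2 (SD, n = 6), in 6 of 6 mice (exact permutation p = 0.0312, the smallest that 6 mice allow). Its difference from the Paneth score was -0.434 ± 0.340 (SD, n = 6), negative in 5 of 6 mice (exact permutation p = 0.0625), which does not pass the 0.05 level. Per mouse the scaled values were 1.18, 0.558, 0.547, 0.894, 0.520 and 0.611. The score of Paneth less LCC was 0.184 and 0.628 in mice 1 and 4, whose LCC arrays correlated best with the others, and 1.23 to 1.73 in the remaining mice. Scaled values divide by this score, and mice 1 and 4, where it was smallest, had the highest ones and raise the mean. The remaining mice lay at 0.520 to 0.611. Of the genes called in YFP-LRC against LCC, 846 of the higher (81.7%) and 86 of the lower (57.3%) were called in the same direction in Paneth against LCC. Independent lists would share 123.9 and 3.80. Both comparisons use the same LCC arrays. Across genes, which are not independent replicates, the 2 sets of fold changes had r = 0.844 with shared LCC arrays, where simulated unchanged groups with shared LCC arrays gave 0.499. Between disjoint sets of 3 mice, which share no LCC array and so lack that source of correlation, r was 0.498 and 0.508. The covariance was 0.114 and 0.110 between the disjoint sets, against 0.0242 in the simulated groups with shared arrays. LCC 2 and 3 fall in the first set and LCC 5 and 6 in the second, so a trend common to these arrays can enter both. The simulated groups drew each gene independently, with 1 spread for all populations, and so hold no such trend. These values cannot separate a likeness of YFP-LRC and Paneth from a trend of the LCC arrays.

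**Figure D4:**
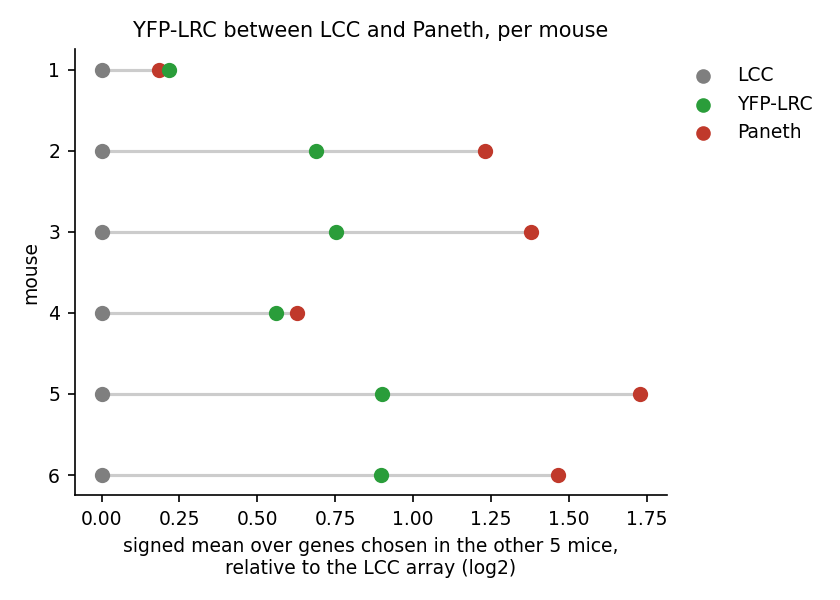
Score of the Paneth and YFP-LRC arrays relative to the LCC array of the same mouse, in log2 units, 1 set of points per mouse. YFP-LRC lies above LCC in 6 of 6 mice and under Paneth in 5 of 6.

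Exon usage asks whether a probe set moved apart from the rest of its gene. The test called 1907 of 10721 genes in YFP-LRC against LCC, 28 of 10857 in YFP-LRC against Paneth and 2665 of 10617 in Paneth against LCC. With an own variance per probe set, 807, 4 and 1741 were called. The lowest adjusted p in both comparisons with LCC was that of Arhgap30 (4.09e-15 in YFP-LRC against LCC and 1.31e-17 in Paneth against LCC). Its probe set changed by -2.79 and -3.27 log2 less the rest of the gene, and the own variance gave adjusted p of 0.000296 and 0.000126. A probe set of Ssbp3 changed by 2.97 log2 less the rest of the gene in YFP-LRC against LCC and by 3.27 in Paneth against LCC (adjusted p = 3.53e-13 and 3.11e-16; 0.0166 and 0.00467 with the own variance). Zfp503 changed by 2.30 in YFP-LRC against LCC (adjusted p = 3.84e-12; 0.00736 with the own variance), and Ryr1 by -2.02 in Paneth against LCC (adjusted p = 3.11e-16; 0.0609). In YFP-LRC against Paneth, Ptprc changed by -2.95 (adjusted p = 5.85e-09), Col4a2 by 1.52 and Col15a1 by -1.96 (adjusted p = 3.09e-07 each), and the own variance gave 0.0648, 0.807 and 1. In simulated data the test made 343 false calls in YFP-LRC against LCC, 18 in YFP-LRC against Paneth and 299 in Paneth against LCC, and the own variance 10, 5 and 15. With 1 spread shared by the populations, diffSplice made 112, 80 and 104. A part of the calls in each comparison is thus in doubt, most of all in YFP-LRC against Paneth, where 28 and 4 genes were called. LCC arrays, with the highest residual spread, enter the other comparisons.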

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

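Within each population or over the mice, 409 sets of 6 values (genes, list means, array measures and position scores) were searched for 1 array far from the other 5, and 19 held one, where chance gives about 1 in 20. There were 6 among 135 sets for Paneth, 5 among 135 for LCC, 8 among 135 for YFP-LRC and 0 among 4 for the mice. Of the tests below, those of scaling, of Lgr5 by itself, and of leukocytes and tuft cells in the Paneth sort were chosen after the result was seen.

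Among Paneth arrays, Mettl1 stood at 8.72 in mouse 5 (others 6.97 to 7.36), Ptpn6 at 10.32 in mouse 5 (8.69 to 9.27), and Ccl6 at 10.96 in mouse 5 (9.80 to 10.21). U2af2 stood at 7.50 in mouse 4 (7.14 to 7.25), Srgn at 4.77 in mouse 6 (5.32 to 5.62) and Gzma at 6.35 in mouse 1 (5.37 to 5.62). Among LCC arrays, ATP6 stood at 11.75 in mouse 1 (12.60 to 13.08), Cdkn1c at 7.03 in mouse 1 (7.45 to 7.64), and Kcnj3 at 6.998 in mouse 5 (6.15 to 6.38). Inpp5d stood at 6.11 in mouse 4 (6.77 to 7.04) and Gzma at 8.48 in mouse 2 (5.67 to 6.69). Among YFP-LRC arrays, mouse 6 had a median correlation of 0.916 (0.939 to 0.950), a secretory progenitor list mean of 7.61 (7.02 to 7.22), Ano10 at 8.12 (7.45 to 7.50) and Spink4 at 12.31 (11.47 to 11.69). Mouse 3 had an enteroendocrine hormone and granule list mean of 8.12 (7.55 to 7.74) and Soat1 at 8.22 (8.76 to 8.93), and mouse 2 had Fabp5 at 7.23 (7.70 to 7.93) and Pyy at 8.01 (7.40 to 7.60).

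Of the genes called between YFP-LRC and LCC, 87.3% were lower in LCC, and 61.6% after a second quantile normalization, so part of the excess moved with scaling. An excess from scaling cannot be told apart from a biological one here. The LCC arrays of mice 2, 3, 5 and 6 also had the lowest correlations and the highest residual spread, which a true difference of the population would move too. Whether poor arrays lower the same genes was tested by the slope of each gene on residual spread in the Paneth arrays against its fold change: across genes, which are not independent replicates, r was 0.0533 (rho 0.0616), with a share of 0.576 of the 720 orders of the 6 arrays as low (SD 0.141), and by the rule first written this counts against quality. That rule was set aside after the result was seen: the Paneth arrays reach a residual spread of 0.404 while the LCC arrays of mice 2, 3, 5 and 6 lie at 0.451 to 0.539, so quality at that level was not tested and cannot be told apart from biology here. A linear trend on residual spread did not take up the whole Lgr5 difference. It was 1.61 ± 0.20 before and 1.28 ± 0.24 with the covariate (8.23 and 5.26 standard errors). With LCC 1 and 4 as the only LCC arrays it was 1.02 ± 0.22 (4.72 standard errors, adjusted p = 0.187). The call ended in both settings, with a smaller fold and a larger error (adjusted p = 0.0599 with the covariate, 9.62e-06 to 0.187 over the alternatives). In all, 7 genes passed the adjustment with the covariate and 4 with LCC 1 and 4. The covariate overlaps with the LCC population, and Lgr5 is among the largest changes, so this does not separate quality from biology.

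Tuft cell genes were higher in the Paneth sort than in YFP-LRC, with a list median of 0.833. Leukocytes in that sort may bring genes such as Ptprc; 34 other leukocyte genes had a median difference of -0.0510 (quartiles -0.180 to 0.107), but this set leaves out Ptprc, which was called, and its median level in Paneth was 5.97 against 6.54 over all genes, so leukocytes cannot be told apart here (the rule first written would have excluded them). Tuft cells in the Paneth sort are a candidate explanation that stays open too. Over the 6 Paneth arrays, the tuft list mean and the mean of 10 genes of no list, picked for the largest excess in Paneth over YFP-LRC and so unable to decide, had r = 0.948 (exact permutation p = 0.00833) and rho = 0.943 (p = 0.0167, exact permutation), and r = 0.957 without the 2 farthest arrays. The Paneth list gave r = 0.918 with the tuft list, so the Paneth arrays share a trend that reaches beyond tuft genes.

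The T cell and myeloid lists were lower in YFP-LRC than in LCC at the preset correlation (adjusted p = 0.0259 and 0.0189) but not with an estimated one (0.144 and 0.105). With fry their adjusted p was 0.0365 and 0.0105. The B and plasma cell list was not called (0.0676), and Tyrobp, lost without LCC 2, 3 or 5 or YFP-LRC 3 or 5 (up to 0.0606), was the 1 called gene. Rgs1, Srgn, Cxcl2 and Il1b were lower in YFP-LRC too, but stand in none of the 3 leukocyte lists and did not enter the test below. Picked for the size of their change, they could not decide it. The 35 genes of the 3 leukocyte lists had a median of -0.16, at percentile 0.51 of 10000 random lists of like expression, and the 16 stromal and endothelial genes a median of -0.15, at percentile 4.06. Leukocytes in the LCC sort and a raised background of low genes on the LCC arrays cannot be told apart by these values, as the medians lie closer than the spread of the random lists and the lists differ in size. The rules first written would have counted the first for leukocytes and excluded background; both were changed for that reason, after the result was seen. The design offers no group that separates these, so no biological explanation was tested.

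Other splits of the same arrays were counted, the real one included. For genes in YFP-LRC against LCC, 2 of 100 splits called as many as the real 1185 (highest other 1445), and 1 of 32 splits that part the arrays of each mouse (highest other 119). Both shares are under 5 of 100, but another split called more genes than the real one, so chance is not clearly excluded. The split with 1445 exchanges LCC 4 with YFP-LRC 6, which points to a structure of the samples. For YFP-LRC against Paneth the counts were 1 of 100 (real 58, highest other 1) and 1 of 32 (highest other 0), so chance is excluded. For Paneth against LCC they were 1 of 100 and 1 of 32 (real 2372, highest other 2295 in both). No other split reached the real count there, but the highest came close to it, so chance is not clearly excluded. The split with 2295 exchanges the Paneth and LCC arrays of mouse 1, which also points to a structure of the samples. For lists, 5 of 100 splits called as many in YFP-LRC against LCC (real 9, highest other 11) and 37 of 100 in YFP-LRC against Paneth (real 6, highest other 10), so chance is not excluded for these counts of lists. In Paneth against LCC, 3 of 100 did (real 10, highest other 10). This is under 5 of 100, but other splits reached the same count, so chance is not clearly excluded. For markers 1 of 100 did (real 233, highest other 1) and for shared calls 1 of 100 (real 932, highest other 1), so chance is excluded for these. For exon usage, 1 of 30 splits did in each comparison (real 1907, 28 and 2665, highest other 1074, 7 and 432). Chance is excluded for the counts in the comparisons with LCC, where simulated data gave 343 and 299 false calls. In YFP-LRC against Paneth, simulated data gave 18 false calls, and 80 with 1 spread shared by the populations. Chance is thus not excluded for those 28 calls.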

How the results depend on the processing

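Leaving out single arrays, LCC arrays 5 and 6 or 2, 3, 5 and 6, the covariate, weights per population and the own-variance exon test were chosen after seeing the data. Counts below are in the order YFP-LRC against LCC, YFP-LRC against Paneth, Paneth against LCC, and those within 1.5 times the reported count are left out. The mean over probe sets gave 1702 higher, 426 lower and 132 2-fold in the first, 83 lower in the second, 1222 lower and 438 2-fold in the third, 90 lower LCC markers and 2 lower Paneth markers. Genes with at least 3 probe sets gave 2 higher LCC markers. Probe sets above the median gave 313 lower in the first and 713 in the third, 17 higher LCC markers and 1 higher YFP-LRC marker (Fabp5). They reversed Fen1 (0.74 in YFP-LRC against LCC, adjusted p = 0.0438; 0.0316 to 0.863 over the alternatives) and Cyp1a1 (-0.73 in Paneth against LCC, adjusted p = 0.0318; 0.0318 to 0.86). Genes above the median gave 223 lower in the third. Quantile normalization gave 378 higher, 236 lower and 125 2-fold in the first, 995, 785 and 366 in the third, and 16 higher and 67 lower LCC markers. Centring gave 610, 295 and 154 in the first, 983 lower in the third, and 8 higher and 98 lower LCC markers; it moved the median difference of all genes from 0.042 to -0.057 in the first and from 0.031 to -0.081 in the third. Array weights gave 95 lower in the second and 1 lower YFP-LRC marker (Cyct), and 12 arrays 381, 34 and 148 in the first and 213 lower in the third. Without LCC 5 and 6, the first gave 194, 31 and 100, the third 858, 157 and 390, lower LCC markers 71, shared calls 167 and 17, and exon usage 1071 in the first and 1554 in the third. Without LCC 2, 3, 5 and 6, the first gave 1, 3 and 4, the second 78 lower, the third 141, 15 and 134, lower LCC markers 0 in limma, shared calls 1 and 3, and exon usage 133, 67 and 192; the G2 and mitosis list in the first reversed (adjusted p = 0.458). With the covariate, the first gave 3, 4 and 7, the third 380, 72 and 313, lower LCC markers 3, shared calls 3 and 4, and the G2 and mitosis list reversed (adjusted p = 0.198; 0.000223 to 0.669 over the alternatives). Weights per population gave 82 lower in the first, 75 lower in the second and 90 for exon usage in the second. An estimated correlation gave 0 called lists in the first and 0 in the third by camera. Shared calls at 2-fold were 194 and 4. On genes lower in Paneth alone, the position score of YFP-LRC less that of Paneth was -0.39. The score is signed by direction, so these genes were on average higher in YFP-LRC than in Paneth. For exon usage, the upper quartile gave 806, 6 and 1068, the own variance 807, 4 and 1741, the F test 17 and at least 5 probe sets 14 in the second. Leaving out 1 mouse or 1 array gave 185 to 1762 higher, 21 to 394 lower and 101 to 569 2-fold in the first, 4 to 9, 19 to 57 and 23 to 51 in the second, and 776 to 2553, 108 to 721 and 394 to 1138 in the third. It gave 2 to 13 higher and 77 to 422 lower LCC markers, 16 to 38 higher and 2 to 5 lower Paneth markers, 0 to 1 higher and 0 to 0 lower YFP-LRC markers, 7 to 12, 5 to 8 and 9 to 11 lists, and a position of 0.570 to 0.772. The extremes of the first were 185 without mouse 5, 1762 and 394 without LCC 1, and 21 without mouse 2 or mouse 5. Of 14542 values for 364 gene results, 13486 stayed on the same side, 863 lost and 191 gained a call and 2 reversed; of 2703 for 66 list results, 2526 stayed, 77 lost, 98 gained and 2 reversed; of 70 for 9 exon results, 63 stayed and 7 lost. The cause of these shifts was not tested, except that fewer arrays or genes enter some of them. The second deposited table is identical, so it tests nothing, and list tests with the mouse as a random block were not run.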

Other observations

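Cell cycle inhibitors and reserve stem cell genes gave values outside the groups described above. Cdkn1c, an inhibitor linked to quiescence, was lower in YFP-LRC than in LCC (-0.50 ± 0.13, adjusted p = 0.0323), a call lost without LCC 2, 3, 5 or 6 or YFP-LRC 1, 2, 4 or 5 (up to 0.0763); it was not called in YFP-LRC against Paneth (-0.46 ± 0.13, adjusted p = 0.287). Cdkn2d was lower as well (-0.55 ± 0.16, adjusted p = 0.0471), a call lost without any 1 of 15 arrays, all but Paneth 1 and LCC 1 and 4 (up to 0.11). Cdkn1a (0.10) and Cdkn1b (0.09) were not called between YFP-LRC and LCC. Lrig1 was higher in YFP-LRC than in LCC (0.87 ± 0.22, adjusted p = 0.027), a call lost without LCC 3, 5 or 6 or YFP-LRC 2, 4 or 5 (up to 0.0661). Bmi1 (-0.49), Tert (-0.18), Hopx (-0.21), Ascl2 (-0.11) and Sox9 were not called in that comparison, nor were Dll1 (0.05), Neurog3 (-0.16), Neurod1 (0.39), Dclk1 (0.62), Notch1 (0.26), Hes1 (0.23) and Cyp1a1 (0.20 ± 0.19, adjusted p = 0.568), whose promoter drove the label. The fatty acid binding gene Fabp2 was lower in YFP-LRC than in LCC (-0.81 ± 0.18, adjusted p = 0.0125). Fut2 (1.28 ± 0.27, adjusted p = 0.00509), Cd82 (1.38 ± 0.40, adjusted p = 0.0257) and Nfatc3 (0.86 ± 0.27, adjusted p = 0.0397) were higher in Paneth than in LCC. Cd82 lost the call without LCC 2, 5 or 6 (up to 0.0644), and Nfatc3 without any Paneth array or LCC 2, 3, 5 or 6 (up to 0.0957). The LCC arrays, with residual spread of 0.320 to 0.539, enter each of these but the Paneth comparison of Cdkn1c.

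Lists not described above had these adjusted p in YFP-LRC against LCC, YFP-LRC against Paneth and Paneth against LCC, and none was called in the test reported. The position +4 or reserve stem cell list had 0.794, 0.548 and 0.927, the Notch pathway list 0.351, 0.25 and 0.161, and the secretory progenitor list 0.597, 0.312 and 0.945. The absorptive enterocyte list had 0.054, 0.831 and 0.107, the cyclin-dependent kinase inhibitor list 0.117, 0.866 and 0.195, and the aryl hydrocarbon receptor target list 0.25, 0.496 and 0.579. The immediate early and dissociation stress list had 0.195, 0.203 and 0.633, and the red blood cell list 0.25, 0.203 and 0.106. The enterocyte list, with medians of -0.15 and -0.37, gained a call in 20 of 41 alternatives for YFP-LRC against LCC (adjusted p 2.22e-07 to 0.658) and in 10 of 41 for Paneth against LCC (4.44e-05 to 0.669). Leaving out Paneth 1, 4 or 5, LCC 4, 5 or 6 or YFP-LRC 1, 2 or 3 was enough in the first, and leaving out Paneth 1 or LCC 4, 5 or 6 in the second. For YFP-LRC against LCC, the tuft cell list gained a call in 14 of 41 (1.96e-09 to 0.669), among them those without Paneth 5, LCC 2, 5 or 6 or YFP-LRC 1 or 4. The S phase list did so in 10 of 41 (0.00692 to 0.843), among them those without LCC 4 or YFP-LRC 1 or 6. In YFP-LRC against Paneth, the G2 and mitosis list did so in 8 of 41 (5.08e-05 to 0.709), among them those without Paneth 3 or 4 or YFP-LRC 2 or 6. In YFP-LRC against LCC, the tuft cell, enteroendocrine transcription factor and enteroendocrine hormone lists had 0.0676, 0.454 and 0.496. The list median, mean and test differed in sign for the reserve stem cell and Notch lists in YFP-LRC against LCC, the enterocyte, kinase inhibitor and T cell lists in YFP-LRC against Paneth, and the secretory progenitor and aryl hydrocarbon receptor lists in Paneth against LCC.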
